A study of Mus musculus with 8 samples.

How the data were processed

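Gene expression was measured on Affymetrix mouse arrays, with 1 array per tumor and total RNA converted to biotin-labelled cRNA, per the labels' protocols. The values used were the deposited log2 expression values of 41345 probe sets on 8 arrays. RMA (background correction, normalization between arrays and a summary per probe set) and Partek 6.6 are named in the submitters' processing notes, which also name R 3.6.1 and DESeq2 1.26.0. No role is given there for these tools. The log2 scale was checked on the values: array medians lay between 4.59 and 4.66 and upper quartiles between 6.14 and 6.38, so the distributions of the arrays were close but not identical. Dim genes sit near the background on such a scale, which compresses their differences. No pair of arrays held identical values (0 pairs), and each of the 8 columns was matched to its tumor by its label.

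Probe sets were named through the platform annotation, updated by gene identifier to the symbols of assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. Of the probe sets, 23521 had 1 gene symbol, 1820 had several and 16004 had none. Only those with 1 symbol were named and tested, which gave 22180 genes. The gene identifiers of 193 probe sets were not matched in the reference and kept the annotation's own symbol. Where a gene had several probe sets (1082 genes), the one with the highest mean over all 8 arrays was taken, and for 1 of these genes different probe sets passed the test in opposite directions. Kras and Ddx3y had no probe set with 1 symbol and were not analysed here.

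The 4 tumors of AKC mice were compared with the 4 tumors of AT mice, as AKC minus AT. Genes were tested with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes moderation, no trend, no robust fit, no filter on dim genes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors of log2 differences are standard errors of that model. The 38 gene lists (pathways, endothelial states and markers of other cell types a bulk tumor could hold) comprised symbols of which 625 were measured and 60 were not. Lists were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated for each list. Both were adjusted over the 38 lists, as was limma's fry, which tests a list by itself. The mean of each list per array was compared by an exact two-sided permutation test over all 70 assignments of arrays, whose smallest possible p is 0.0286. Each list's member counts are also given with p adjusted over the list alone. The number of arrays limits the precision, and no depth applies to them.

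The genes named are the engineered genes and their partners, whatever their values. They also include the 12 with the largest fold in either direction among genes past the threshold whose arrays did not overlap between the groups, leaving out unnamed gene models, microRNAs and small nucleolar RNAs with standard names, ribosomal RNA genes, receptor multigene families, major urinary proteins and antigen receptor segments. Of each list, up to 4 members with the smallest p are named, and all members past the threshold where these number 5 or fewer. The lists, tests, naming rule and most alternatives were chosen before the data were examined. For genes that lay below the background level on every array of a group, only a bound, written "at least", or no size is given. The background level of an array was the 95th percentile of its 1105 olfactory receptor genes (4.36 to 4.56), a level chosen after the data were seen. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of that level and the gene's own value. Genes below that level on only some arrays of a group keep their fitted difference, which is less certain there. Besides those named with such a count beside their values, these were Bmx (1 AKC array), Sema3d (3) and Cd8a (2), and Apln and Ptgs2 (3 AT arrays each), Cd163 and Mir409 (2 each), Elovl6 and Oasl2 (1 each) and Psg22 (3). Myoz1 was below it on 1 AKC and 3 AT arrays, Xist on 3 and 2 and Eif2s3y on 1 and 2. Some genes given a bound were also below that level on part of the brighter group. Besides C1qtnf3 and Myh4, these were Il6, Cyp2e1 and Prl8a9 (2 AKC arrays each) and Plagl1, Zim1 and Cts8 (1 each). Cd27 was below it on 1 AT array and Jchain on 2.

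The alternatives were quantile normalization or median centring of the arrays, leaving out the dimmest 33.3% or 50% of genes, the mean of a gene's probe sets, a trended robust fit, array weights, the replicate number as a block, all probe sets, stricter thresholds, and each array left out in turn. Lists were also summarised by their medians. Added after the data were seen were a fit with Eif2s3y as a covariate for sex, a fit with the skeletal muscle list mean as a covariate, and a fit without AKC replicate 3 and AT replicate 2. The gene test was tested on simulated data for this comparison, with 22180 genes and 50 changed at each size. It recovered 20% of genes changed by 0.5 on the log2 scale, 72% at 1, 88% at 2 and 98% at 4, and called 6 of 21980 unchanged genes. Camera found the simulated list that moved and called 0 of the 37 others. The simulated genes varied independently of each other, whereas the estimated correlation within the real lists reached 0.877. The simulation therefore does not check camera at the preset correlation on correlated genes. It also changed far fewer genes than the 3527 called in the real data and gave both groups the same spread. Its recovery rates therefore need not hold for the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.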

Results

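The series compared 2 kinds of vascular tumor that arose spontaneously in mice carrying the aP2-Cre transgene, which expresses Cre recombinase from the promoter of the fatty acid binding protein gene Fabp4. AKC mice combined the transgene with a Cre-activated mutant Kras allele and floxed Cdkn2a, and their tumors were labelled angiosarcoma, a malignant tumor of endothelium. AT mice combined it with floxed Tsc1, and the tissue label of their tumors reads "KHE - angiosarcoma". Each group held 4 tumors, which the labels call biological replicates from separate mice on a mixed genetic background, and 22180 genes were tested on 8 arrays. The question posed by the design was how tumors of the 2 genotypes differ in gene expression. The number of arrays limits the precision of each value.

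AKC tumors had far lower expression of lymphatic endothelial genes than AT tumors, lower expression of general endothelial genes, and higher expression of extracellular matrix, smooth muscle and macrophage genes. These 5 lists passed camera with a preset correlation and not with an estimated one, where the adjusted p was 0.0619 for lymphatic, 0.476 for general endothelial, 0.476 for matrix, 0.670 for smooth muscle and 0.524 for macrophage genes. The smooth muscle list had an adjusted p of 0.173 with the skeletal muscle mean as a covariate. Prox1, the transcription factor that specifies lymphatic endothelium, averaged 3.94 ± 0.37 in AKC and 10.44 ± 0.34 in AT tumors (log2, SD, n = 4 each). It was at least 63.0-fold lower in AKC. Col1a1, the main chain of type I collagen, averaged 12.24 ± 0.40 in AKC and 9.11 ± 0.58 in AT tumors. In total 3527 genes passed the adjusted threshold, 1403 higher and 2124 lower in AKC, so that 39.8% were higher. With quantile normalization between arrays the split was 1860 higher and 1733 lower, or 51.8% higher. A change of at least 1 on the log2 scale was shown by 637 of the higher and 903 of the lower genes. The 4 AKC values lay entirely above or below the 4 AT values for 5172 genes, 23.3% of those tested, where chance gives 2.86%, and 3355 of the called genes were among them.

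Arrays of AT tumors resembled each other more closely than those of AKC tumors. Pearson's r across genes, which are not independent replicates, was 0.981 to 0.989 over the 6 pairs of AT arrays and 0.941 to 0.982 over the 6 pairs of AKC arrays. Between the groups it was 0.895 to 0.945 over 16 pairs. The first principal component held 56.6% of the variance and separated the groups, and the next components held 16.1% and 11.6%. The count of called genes was 2149 without AT replicate 1 and 2055 without AT replicate 4, and 1989 with the skeletal muscle list mean as a covariate. Of 149 named genes past the threshold, 85 kept their call under each alternative fit that included them, 77 of these also with an adjusted p under 0.01 and a change of at least 1 on the log2 scale, while 47 lost it when some single array was left out and 55 with the muscle covariate. The muscle mean partly followed the groups (r = 0.673), which widens the error of the group difference. Calls lost with this covariate therefore need not reflect muscle RNA. Most named genes were picked by large differences or small p in the same data, so their stability need not hold for all called genes. Of the 3527 called genes, 2026 stayed called without AT replicate 4 and 1624 with the muscle covariate.

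**Figure D1:**
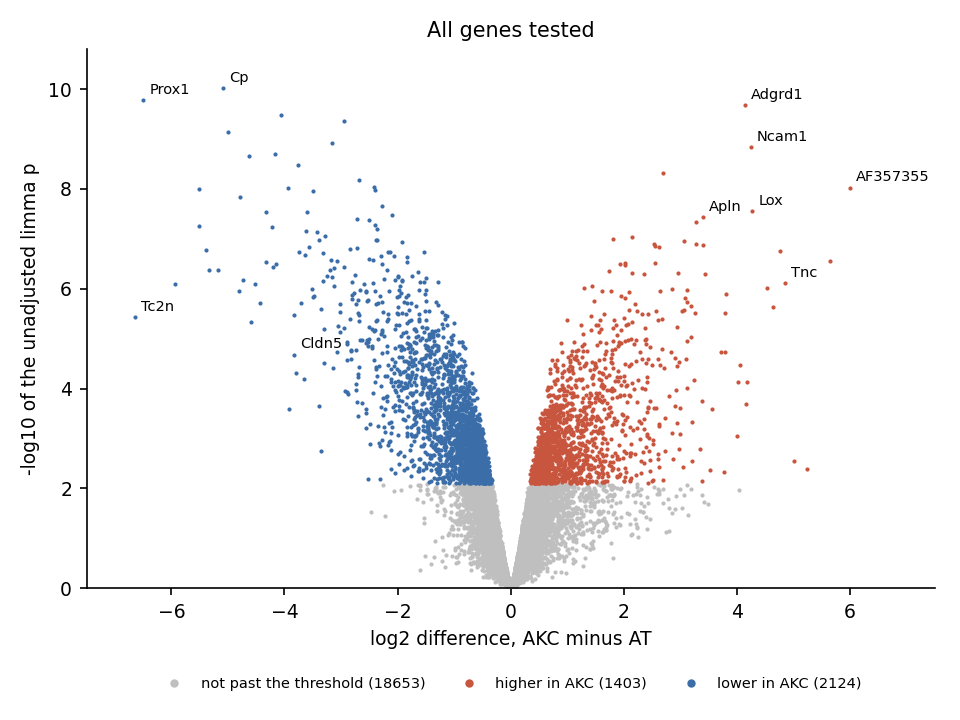
Each point is 1 of the 22180 genes, with the log2 difference (AKC minus AT) on the horizontal axis and the -log10 of the unadjusted limma p on the vertical axis. The coloured points are the 1403 genes higher and the 2124 genes lower in AKC past the adjusted threshold.

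Of the genes altered by breeding, Cdkn2a, which encodes cell cycle inhibitors, differed by 0.22 ± 0.12 (log2, adjusted p = 0.244), and Tsc1, a brake on mTORC1 signalling, by 0.02 ± 0.13 (adjusted p = 0.918). Tsc2, the partner of Tsc1, differed by -0.26 ± 0.14 (adjusted p = 0.245). Cdkn2b, the neighbouring inhibitor gene, was higher in AKC by 0.96 ± 0.22 (adjusted p = 0.0168, 0.0514 without AT replicate 3 and 0.107 with the muscle covariate). Where the probes lie relative to the deleted parts is not given in the sources used here, so these values check nothing about the deletions. Of the 4 measured genes of this list 1 was higher, as it was when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.495). It passed fry (adjusted p = 0.0265), and its mean was at the smallest exact permutation p (0.0286, adjusted p = 0.0835).

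The largest increases in AKC included a pair of small nucleolar RNAs, AF357355 (6.00 ± 0.32, below background on 3 of 4 AT arrays) and AF357425 (5.64 ± 0.43, on 2 of 4), and the long noncoding RNA Rian, at least 17.4-fold higher (adjusted p = 7.26e-05). Genes of matrix and adhesion followed: tenascin C (Tnc, 4.86 ± 0.42), the collagen-crosslinking enzyme Lox (4.28 ± 0.25) and the adhesion molecule Ncam1 (4.25 ± 0.18). Desmin (Des), an intermediate filament of muscle cells, was higher by 4.18 ± 0.62 and arginase 1 (Arg1) by 4.17 ± 0.71. The adhesion receptor Adgrd1 was at least 13.3-fold higher, the prolactin family gene Prl5a1 at least 11.8-fold and the stefin family gene Csta3 at least 7.23-fold. The secreted factor C1qtnf3 was at least 22.3-fold higher on average (adjusted p = 0.0258), with 4.40 on AKC replicate 2, below the background level, against 9.70 to 11.09 on the other 3 AKC arrays. It lost its call under 9 of 19 alternatives, with adjusted p up to 0.213, and among single omissions kept it only without AKC replicate 2.

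The 12 genes with the largest fitted decreases included Prox1, Tc2n (-6.65 ± 0.69) and Klrb1f, a lectin-like receptor of natural killer cells (-5.94 ± 0.52). Klhl4 (-5.51 ± 0.35), Pkhd1l1 (-5.38 ± 0.39) and the membrane glycoprotein gene Gpm6a (-5.34 ± 0.43) were lower too. The secreted glycoprotein reelin (Reln) was lower by 5.17 ± 0.42. Ceruloplasmin (Cp), the copper-carrying ferroxidase, averaged 5.40 ± 0.26 in AKC and 10.48 ± 0.22 in AT tumors (SD, n = 4 each). Slc45a3 (-5.00 ± 0.20), the growth factor Gdf10 (-4.81 ± 0.43), neurotensin (Nts, -4.79 ± 0.26) and Pgm5 (-4.74 ± 0.40) completed the 12. Because many of these genes lay near background in AKC tumors, their order is uncertain. Tc2n, Klrb1f, Pkhd1l1 and Reln were below background on 3 of 4 AKC arrays, Klhl4 and Gpm6a on 2, and Slc45a3, Gdf10 and Pgm5 on 1. Adjusted p over these 12 genes ran from 1.55e-06 for Prox1 and Cp to 0.000405 for Tc2n.

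**Figure D2:**
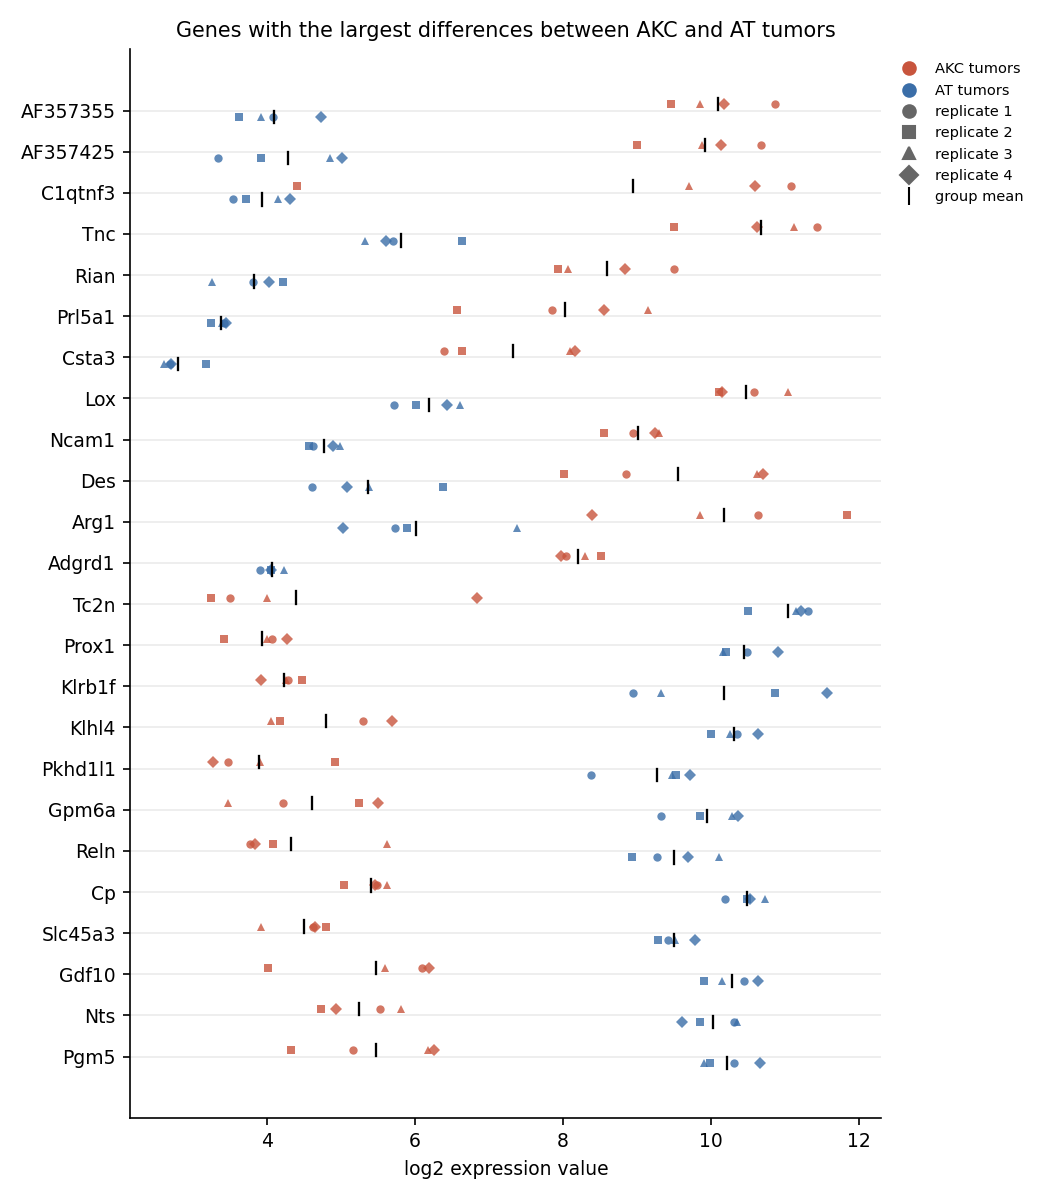
Log2 expression on each array of the genes with the largest differences in either direction, with AKC and AT tumors in different colours, replicates as different markers and a bar at each group mean. The AKC and AT arrays do not overlap for any gene shown, and C1qtnf3 on AKC replicate 2 (4.40) lies close to the AT arrays.

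Of the 38 lists, 15 passed camera, 8 higher and 7 lower in AKC, and 11 passed fry, 10 of them among the 15 and the other being the list of engineered genes and their partners. With estimated correlations 0 passed, against 3 at an unadjusted p under 0.05. Of the 35 ways to divide the 8 arrays into 4 and 4, 16 gave at least 15 lists, so the number of lists alone does not exceed what other divisions give. Mean values of 13 lists reached the smallest exact permutation p of 0.0286, and 0 passed after adjustment (smallest adjusted p = 0.0835).

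Lymphatic endothelial genes fell most. Of 13 measured, 11 were lower in AKC and 0 higher, with a median of -3.03, and adjusted over the list alone 11 were lower and 1 higher. Besides Prox1, Reln and Nts, the guidance factor Sema3d was lower (-4.33 ± 0.26), as was the transcription factor Tbx1 (-3.49 ± 0.19). The other 2 members did not pass: the hyaluronan receptor Lyve1 differed by 1.63 ± 0.63 (adjusted p = 0.112) and podoplanin (Pdpn) by 0.35 ± 0.25 (adjusted p = 0.392). Both were chosen after their values were seen. The list mean was 6.70 ± 0.22 in AKC and 9.60 ± 0.18 in AT tumors (SD, n = 4 each; exact permutation p = 0.0286). Camera gave an adjusted p of 1.35e-11, and with an estimated correlation the adjusted p was 0.0619.

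General endothelial genes were lower too: 22 of 29 were lower and 0 higher, with a median of -1.76, and adjusted over the list alone 24 were lower. The tight junction gene Cldn5 (-3.83 ± 0.49), Egfl7 (-2.27 ± 0.25), Myct1 (-2.19 ± 0.18) and the sphingosine phosphate receptor S1pr1 (-1.80 ± 0.18) had the smallest p. The adhesion molecule Pecam1 (-1.36 ± 0.29) and the VEGF receptor Kdr (-2.33 ± 0.51), chosen after their values were seen, were lower as well, and Kdr had an adjusted p of 0.0512 without AT replicate 4. Pecam1 (adjusted p = 0.0697) and Kdr (0.0677) also lost their calls with both AKC replicate 3 and AT replicate 2 left out. The list mean was 7.64 ± 0.73 in AKC and 9.32 ± 0.09 in AT tumors. Camera gave an adjusted p of 6.50e-15, and the adjusted p was 0.476 with an estimated correlation.

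Arterial and Notch genes were lower for 9 of 18 and higher for 1, with the same counts adjusted over the list alone. The arterial kinase gene Bmx (-2.71 ± 0.17), the connexin Gja4 (-2.27 ± 0.29), the Notch ligand Jag2 (-1.23 ± 0.16) and the Notch target Hes1 (-1.21 ± 0.18) fell. Nrp1, a co-receptor for VEGF and semaphorins and chosen after its value was seen, was the 1 member that rose (1.34 ± 0.34), with adjusted p up to 0.0814 when single arrays were left out and 0.242 with the muscle covariate. The list's median was -0.67, with an adjusted p of 0.00106 by camera and 0.670 with an estimated correlation. Venous genes went both ways, with 2 of 9 higher and 3 lower, or 2 and 4 adjusted over the list alone. The apelin receptor Aplnr (2.62 ± 0.51) and Il1r1 (1.54 ± 0.29) rose, and Ephb4 (-2.74 ± 0.34), the venous regulator Nr2f2 (-1.76 ± 0.28) and Vcam1 (-1.58 ± 0.35) fell, with an adjusted p of 0.0895 for Aplnr with the muscle covariate. The median was -0.43, and the list did not pass camera (adjusted p = 0.199). Among genes of angiogenic tip cells 5 of 19 were higher and 3 lower, or 7 and 3 adjusted over the list alone. Apelin (Apln, 3.41 ± 0.21) and Kcne3 (2.09 ± 0.34) rose while the growth factors Pgf (-2.55 ± 0.30) and Angpt2 (-2.39 ± 0.36) fell. That median was 0.54 and the camera adjusted p 0.135.

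**Figure D3:**
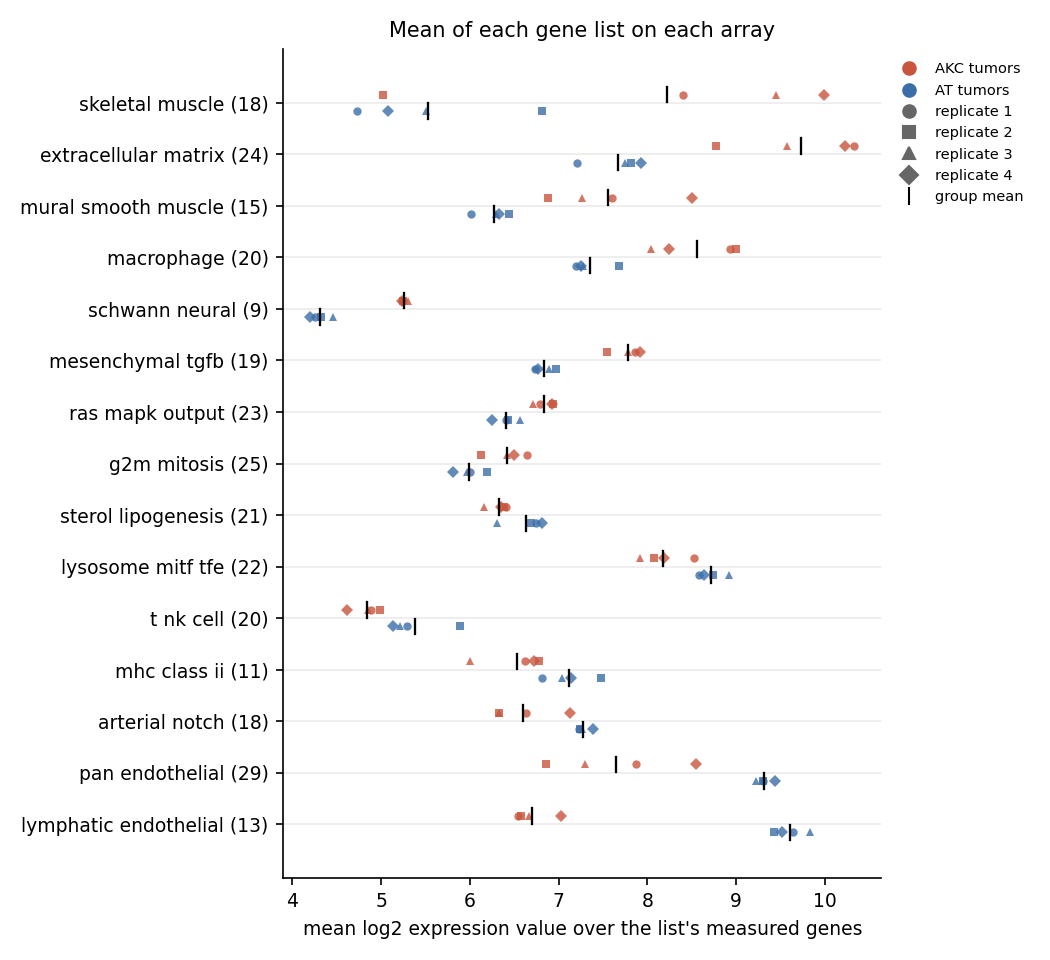
Mean log2 expression of the measured members of gene lists on each array, with AKC and AT tumors in different colours, replicates as different markers and a bar at each group mean. For lymphatic endothelial genes the group means are 6.70 in AKC and 9.60 in AT, and the skeletal muscle list ranges from 5.02 to 9.99 among AKC tumors.

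Targets of RAS and MAPK signalling were higher in AKC: 5 of 23 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median of 0.38. These were the growth factor gene Hbegf (1.50 ± 0.20), Phlda1 (1.43 ± 0.16), the ETS factor Etv5 (0.87 ± 0.19), Myc (0.78 ± 0.17) and the feedback inhibitor Spry2 (0.62 ± 0.13). Etv5 had an adjusted p of 0.0515 without AT replicate 4. Spry2 (adjusted p = 0.135) and Myc (0.0999) lost their calls with the muscle covariate, and Spry2 (0.0507) also with both AKC replicate 3 and AT replicate 2 left out. The camera adjusted p was 0.00178, and 0.476 with an estimated correlation. Immediate early genes did not move together, with 1 of 17 higher and 1 lower, or 1 and 0 adjusted over the list alone. Egr2 rose (0.87 ± 0.15) and the phosphatase gene Dusp1 fell (-1.09 ± 0.32), the latter without a call under 13 of 19 alternatives (6 of 8 single omissions), with adjusted p up to 0.226, and Egr2 had 0.0524 with the muscle covariate. The list's median was -0.13 (camera adjusted p = 0.504).

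Lysosomal genes and their MiT/TFE-linked regulators were lower in AKC, 6 of 22 against 0 higher, or 9 and 0 adjusted over the list alone. The Rag GTPases Rragd (-1.92 ± 0.32) and Rragc (-0.79 ± 0.20), the autophagy gene Uvrag (-0.99 ± 0.17) and the proton pump subunit Atp6v1h (-0.77 ± 0.18) fell. Atp6v1h had an adjusted p of 0.0509 without AT replicate 1, and that of Rragc reached 0.0809 with any of AKC replicate 2 or AT replicates 1, 3 or 4 left out. Both lost their calls as well with the muscle covariate (0.153 and 0.127) and with both AKC replicate 3 and AT replicate 2 left out (0.0558 and 0.0665), and Rragc with the replicate block (0.0535). The median was -0.45, with an adjusted p of 0.000825 by camera 0.0505 without the dimmest 50% of genes and 0.524 with an estimated correlation. Of 21 genes of sterol and fatty acid synthesis 6 were lower and 1 higher, or 9 and 2 adjusted over the list alone. The cholesterol transfer gene Stard4 (-1.38 ± 0.16), Sc5d (-0.99 ± 0.16) and the sterol regulator Srebf2 (-0.75 ± 0.11) fell, and the elongase Elovl6 rose (0.73 ± 0.15). The median was -0.48 (camera adjusted p = 0.0122, adjusted p = 0.709 with an estimated correlation and 0.0528 to 0.0914 under 5 other alternatives). Elovl6 had an adjusted p of 0.0803 with the muscle covariate. Targets of ATF4 and amino acid metabolism rose for 7 and fell for 3 of 22 genes, or 8 and 3 adjusted over the list alone. The amino acid transporter Slc7a5 (2.61 ± 0.62), Aldh18a1 (1.19 ± 0.23) and Psat1 (0.93 ± 0.21) were higher and the mTORC1 inhibitor Ddit4 lower (-2.44 ± 0.27). Psat1 had an adjusted p of 0.0502 without AT replicate 3, and that of Slc7a5 reached 0.0654 without AT replicate 1, 3 or 4. With the muscle covariate these were 0.148 and 0.112, and that of Psat1 was 0.0565 with both AKC replicate 3 and AT replicate 2 left out. That list's median was 0.49 (camera adjusted p = 0.0874).

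Some mitotic genes were higher: 4 of 25 rose and 0 fell, the same counts adjusted over the list alone, with a median of 0.29. They were Ube2c (1.99 ± 0.49), the kinases Plk1 (0.90 ± 0.18) and Cdk1 (0.87 ± 0.19), and Tpx2 (0.62 ± 0.16). When single arrays were left out, adjusted p reached 0.0733 for Ube2c, 0.0512 for Cdk1 and 0.0877 for Tpx2. None of the 4 kept its call with the muscle covariate (adjusted p 0.105 for Plk1, 0.134 for Ube2c, 0.166 for Cdk1 and 0.261 for Tpx2), and Tpx2 lost it with the replicate block (0.0746). The camera adjusted p was 0.00178, 0.709 with an estimated correlation and 0.108 with fry. The list mean was 6.12 on AKC replicate 2 and 6.20 on AT replicate 2, so the groups overlapped (exact permutation p = 0.0571). With the skeletal muscle list mean as a covariate the adjusted p was 0.436. That mean itself had an exact permutation p of 0.114 between the groups and a correlation of r = 0.673 with them. Of 20 S phase genes, E2f1 (0.39 ± 0.11) and Rrm2 (0.71 ± 0.20) were higher and 0 lower, but adjusted over the list alone 0 passed, against 6 at an unadjusted p under 0.05. Single omissions ended the call of E2f1 in 7 of 8 cases and that of Rrm2 in 6, with adjusted p of 0.108 and 0.129 with the muscle covariate. That median was 0.24 (camera adjusted p = 0.0986). Targets of p53 went both ways, 2 of 18 higher and 3 lower, or 5 and 6 adjusted over the list alone. The cyclin gene Ccng1 (2.40-fold) and the BH3-only gene Pmaip1 (0.62 ± 0.14) rose, and Plk2 (-2.23 ± 0.19), the death receptor Tnfrsf10b (-1.56 ± 0.23) and Trp53inp1 (-0.84 ± 0.10) fell. The adjusted p of Pmaip1 reached 0.0551 without AT replicate 1 or 4 and 0.0603 with the muscle covariate. The list's median was positive (0.27) while its mean (-0.07) and the camera direction were negative (adjusted p = 0.971).

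In glycolysis and hypoxia genes 1 of 19 was higher, the collagen hydroxylase subunit P4ha1 (1.29 ± 0.34), and 1 lower, Ndrg1 (-2.18 ± 0.36), the same counts adjusted over the list alone. The adjusted p of P4ha1 reached 0.0981 without AKC replicate 1 or 2 or AT replicate 1 or 4 and was 0.0631 with both AKC replicate 3 and AT replicate 2 left out. That of Ndrg1 was 0.0513 with the muscle covariate. The median was 0.21 (camera adjusted p = 0.485). By limma 0 of 19 ribosome biogenesis genes and 0 of 25 oxidative phosphorylation genes passed, also adjusted over the list alone, against 5 and 8 at an unadjusted p under 0.05. Their medians were 0.14 (camera adjusted p = 0.343) and 0.15 (camera adjusted p = 0.0607).

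Extracellular matrix genes rose in AKC: 18 of 24 were higher and 0 lower, or 20 and 0 adjusted over the list alone, with a median of 1.97. Besides Lox, the collagens Col5a1 (3.40 ± 0.24) and Col1a1 (3.13 ± 0.30) were examples, and the list included the fibroblast receptor Pdgfra (2.57 ± 0.26). The list mean was 9.73 ± 0.72 in AKC and 7.67 ± 0.32 in AT tumors. Camera gave an adjusted p of 4.03e-14, and the adjusted p was 0.476 with an estimated correlation. Of 19 genes of mesenchymal identity and TGF-beta response 8 were higher and 1 lower, or 11 and 2 adjusted over the list alone. Tnc, N-cadherin (Cdh2, 2.02 ± 0.16) and the matricellular gene Ccn2 (1.67 ± 0.23) rose, and activin A subunit Inhba was at least 3.41-fold higher. S100a4, chosen after its value was seen, was the member that fell (-1.34 ± 0.30), and its adjusted p reached 0.0534 without AT replicate 1 or 4 and 0.0982 with the muscle covariate. The median was 0.91 (camera adjusted p = 0.000829, and adjusted p = 0.163 with an estimated correlation).

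Mural and smooth muscle genes were higher for 5 of 15 and lower for 1, or 8 and 1 adjusted over the list alone, with a median of 0.87. Smooth muscle actin (Acta2, 3.09 ± 0.29) and transgelin (Tagln, 3.07 ± 0.21) rose with Des, and calponin (Cnn1) was at least 6.11-fold higher. The pericyte gene Cspg4 rose (1.20 ± 0.32) and smoothelin (Smtn) fell (-0.77 ± 0.21), both chosen after their values were seen. Cspg4 lost its call under 8 of 19 alternatives (5 of 8 single omissions, adjusted p up to 0.278) and Smtn under 9 (6 of 8, up to 0.113). The camera adjusted p was 0.000829, with 0.670 as the adjusted p with an estimated correlation and 0.173 with the skeletal muscle mean as a covariate. Skeletal muscle genes themselves varied widely among AKC tumors, with list means of 8.40, 5.02, 9.45 and 9.99 in replicates 1 to 4, against 4.73, 6.82, 5.51 and 5.08 in AT tumors. Of 18, 4 were higher and 0 lower, or 11 and 0 adjusted over the list alone. The median was 2.78 (camera adjusted p = 0.000152, adjusted p = 0.709 with an estimated correlation and 0.140 with fry). Fast myosin Myh4 was at least 18-fold higher on average, and creatine kinase (Ckm, 3.38 ± 0.98), troponin I (Tnni2, 2.70 ± 0.78) and Myoz1 (2.50 ± 0.73) rose. On AKC replicate 2 Myh4 was 3.65, below background and within the AT range, against 9.11 to 11.25 on the other AKC arrays. Single omissions ended the calls of Myh4, Ckm and Myoz1 in 7 of 8 cases each and that of Tnni2 in 6, with adjusted p up to 0.121. With the muscle covariate, which holds these genes, none of them was called.

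Macrophage genes rose: 11 of 20 were higher and 1 lower, or 13 and 1 adjusted over the list alone, with a median of 1.08. The integrin Itgam (2.92 ± 0.46), the Fc receptor Fcgr1 (2.38 ± 0.28), the scavenger receptor Cd163 (2.19 ± 0.34) and Trem2 (1.83 ± 0.34) were examples. Mertk, a receptor for uptake of dying cells and chosen after its value was seen, fell (-0.94 ± 0.23), with an adjusted p of up to 0.0712 without AT replicate 2, 3 or 4, and of 0.0600 with the replicate block and 0.161 with the muscle covariate. The list mean was 8.55 ± 0.48 in AKC and 7.35 ± 0.22 in AT tumors. The camera adjusted p was 1.16e-05, and 0.524 with an estimated correlation. Of 13 neutrophil genes the protease Mmp9 was higher (2.03 ± 0.38) and 0 were lower, or 3 and 0 adjusted over the list alone, with a median of 1.15 (camera adjusted p = 0.0503).

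T and NK cell genes were lower for 5 of 20 and higher for 0, or 8 and 0 adjusted over the list alone, with a median of -0.63. They were Cd8a (-1.35 ± 0.39), Cd4 (-1.06 ± 0.26), perforin (Prf1, -0.93 ± 0.26), Cd5 (-0.91 ± 0.17) and Cd27, at least 1.05-fold lower. Single omissions ended the calls of Cd8a and Prf1 in 6 of 8 cases each, that of Cd27 in 5 and that of Cd4 in 4, with adjusted p up to 0.101. Over all alternatives adjusted p reached 0.243 for Cd8a, 0.126 for Cd27, 0.120 for Cd4, 0.114 for Prf1 and 0.0682 for Cd5, and none of the 5 was called with the muscle covariate. The camera adjusted p was 0.00116, 0.524 with an estimated correlation and 0.0834 with fry. AT replicate 2, which also had the highest keratinocyte list mean (5.55), had the highest T and NK list mean (5.89). MHC class II and dendritic cell genes were lower for 1 of 11, the dendritic cell factor Zbtb46 (-1.07 ± 0.14), and for 7 adjusted over the list alone, with 0 higher. H2-Aa differed by -1.20 ± 0.37 (adjusted p = 0.0560, and 0.0409 to 0.0455 with either filter on dim genes or the replicate block). The median was -0.41 (camera adjusted p = 0.00424, adjusted p = 0.670 with an estimated correlation and 0.0549 to 0.0905 under 3 other alternatives). Of 12 checkpoint genes Cd80 (0.94 ± 0.21) and Havcr2 (0.86 ± 0.18) rose and Lag3 fell (-0.72 ± 0.15), or 2 and 3 adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.387). The adjusted p of Cd80 reached 0.0534 without AT replicate 1, 3 or 4, that of Havcr2 was 0.0899 with the muscle covariate and that of Lag3 0.0662 with both AKC replicate 3 and AT replicate 2 left out.

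Interferon response genes divided, with 4 of 18 higher and 3 lower, or 5 and 4 adjusted over the list alone, and a median of 0.18 (camera adjusted p = 0.669). The antiviral genes Rsad2 (3.01 ± 0.62), Oasl2 (2.81 ± 0.46) and Oas2 (2.50 ± 0.34) and the regulator Irf7 (1.96 ± 0.40) rose. The antigen processing genes Tap1 (-1.34 ± 0.31), Psmb8 (-1.04 ± 0.27) and Psmb9 (-0.98 ± 0.26), chosen after their values were seen, fell. Psmb8 and Psmb9 lost their calls in 5 of 8 single omissions each, with adjusted p up to 0.0956. Psmb9 (adjusted p = 0.190), Psmb8 (0.176), Tap1 (0.106) and Irf7 (0.0836) lost them with the muscle covariate. Inflammatory NF-kB genes were higher for 4 of 19 and lower for 2, or 5 and 2 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.0667). The prostaglandin synthase Ptgs2 (3.80 ± 0.38) and the chemokine Ccl7 (1.70 ± 0.37) rose, as did Ccl3 (1.35 ± 0.38) and Il6 (at least 1.24-fold), both chosen after their values were seen. The chemokine Ccl5 (-1.08 ± 0.29) and the inhibitor Nfkbia (-0.995 ± 0.27) fell. Single omissions ended the calls of Ccl3 and Nfkbia in 6 of 8 cases each, that of Il6 in 5 and that of Ccl5 in 4, with adjusted p up to 0.118. Nfkbia (adjusted p = 0.313), Ccl7 (0.142), Ccl3 (0.0663) and Ccl5 (0.0630) lost theirs with the muscle covariate, and Il6 (0.150) with both AKC replicate 3 and AT replicate 2 left out.

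Of 12 B and plasma cell genes Jchain fell, at least 1.33-fold (no call in 6 of 8 single omissions, adjusted p up to 0.134 over all alternatives), but 0 passed adjusted over the list alone, against 1 at an unadjusted p under 0.05, and the median was -0.00 (camera adjusted p = 0.428). By limma 0 of 9 mast cell genes (median 0.23, camera adjusted p = 0.253) and 0 of 6 erythroid genes (median 1.23, camera adjusted p = 0.409) passed, also adjusted over the list alone, against 1 in each at an unadjusted p under 0.05. Of 11 platelet genes Pf4 rose (2.68 ± 0.28) and 0 fell, the same adjusted over the list alone (median 0.23, camera adjusted p = 0.298). Of 15 adipocyte genes Plin4, a lipid droplet coat protein, fell (-2.11 ± 0.48) and 0 rose, the same adjusted over the list alone (median 0.17, camera adjusted p = 0.718). Fabp4, whose promoter drives the transgene, differed by -0.89 ± 0.46 (adjusted p = 0.232, and -2.01 with an adjusted p of 0.00778 with the muscle covariate) and was chosen after its value was seen.

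By limma 0 of 16 keratinocyte genes passed, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. The median was -0.15 (camera adjusted p = 0.485), and Krt1, below background on all AKC arrays, did not pass (adjusted p = 0.338). Of 13 genes of simple epithelium, the keratins Krt8 (0.80 ± 0.17), Krt7 (0.38 ± 0.11) and Krt19 were higher, the last below background in both groups, and Prom1 was at least 4.36-fold lower, the same counts adjusted over the list alone. This list's median (0.14) and camera direction were positive and its mean (-0.01) negative (adjusted p = 0.412). Krt7 and Krt19 lost their calls in 7 of 8 single omissions each, with adjusted p up to 0.121 and 0.109 over all alternatives, and Krt8 had 0.0695 with both AKC replicate 3 and AT replicate 2 left out. Of 13 hepatocyte genes, haptoglobin (Hp, 2.23 ± 0.44) and Cyp2e1 (at least 1.12-fold) rose and 0 fell, or 2 and 1 adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.226). Cyp2e1 lost its call in 6 of 8 single omissions, with adjusted p up to 0.350 over all alternatives. Of 9 Schwann and neural genes Ncam1 and the neurofilament gene Nefl (at least 1.38-fold) rose and 0 fell, the same adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.000825, and adjusted p = 0.145 with an estimated correlation). By limma 0 of 4 sex-linked genes passed, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. The median was 0.66 (camera adjusted p = 0.880), with Xist differing by -1.60 ± 1.95 and Eif2s3y by 0.98 ± 1.40. On AKC replicate 2 and AT replicates 1 and 2, Xist was 9.61, 9.89 and 9.93 and Eif2s3y 3.49, 3.39 and 3.01, the pattern of females. On all other arrays Xist was 3.26 to 3.74 and Eif2s3y 7.43 to 8.23, the pattern of males. Both groups thus held both sexes by these genes, though sex was not labelled.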

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

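All tests weighed here, except the counts over other divisions of the arrays, were chosen only after the result was seen. A value was singled out when the highest or lowest of the 4 arrays of a group lay so far from the nearest other that this gap took up more of the group's range than Dixon's 95% critical value. Chance singles out about 1 in 20 groups: of 400 groups tested, 25 met the criterion where 20 would by chance. By array, AT replicate 2 had 8 of them, AKC replicate 2 and AT replicate 4 had 5 each, AKC replicate 3 had 4, and AKC replicate 4, AT replicate 1 and AT replicate 3 had 1 each.

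On AT replicate 2 the high log2 values were Krt1 at 7.04 (3.80 to 4.10 on the other AT arrays), Tnni2 at 7.05 (5.32 to 5.55), Myoz1 at 5.02 (3.92 to 4.01) and Csta3 at 3.17 (2.61 to 2.70). List means high on that array were keratinocyte at 5.55 (3.88 to 4.06), venous endothelial at 7.41 (7.05 to 7.07), macrophage at 7.68 (7.20 to 7.28) and mast cell at 4.34 (3.91 to 3.98). On AKC replicate 2, Xist was high at 9.61 (3.26 to 3.74 on the other AKC arrays) and Eif2s3y low at 3.49 (7.43 to 7.82), the pattern of a female also seen on AT replicates 1 and 2. There too Nfkbia was high at 9.46 (8.26 to 8.43 on the other AKC arrays), and Tpx2 was low at 6.70 (7.17 to 7.23) and Ndn at 5.47 (6.47 to 6.55) on AKC replicate 2. On AKC replicate 3, Uvrag was low at 7.57 (8.20 to 8.29), Mertk at 7.37 (8.24 to 8.39) and H2-Aa at 6.70 (8.20 to 8.27), and the Schwann list mean was high at 5.31 (5.23 to 5.24). Mmp9 was low on AKC replicate 4 at 7.01 (8.57 to 8.63). On AT replicate 4, Tsc2 was high at 8.09 (7.67 to 7.71) and Psg22 at 4.595 (4.37 to 4.41), and Il6 was low at 3.35 (3.69 to 3.75), Pf4 at 6.27 (6.74 to 6.81) and Hp at 5.61 (6.19 to 6.28). Pgf was high on AT replicate 3 at 10.18 (9.38 to 9.51), and Col5a1 low on AT replicate 1 at 6.03 (6.68 to 6.81).

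The count of called genes was tested over the 35 divisions of the 8 arrays into 4 and 4. Only 1 of 35, the real one, gave as many as 3527 genes, and the highest count among the others was 0. The real division thus stood out, and 1 of 35 is the smallest share this test can give. All other divisions mix AKC and AT arrays, which adds the difference between the groups to the spread within them and lowers their counts. The test also cannot tell the genotype from anything else that followed the groups. For gene lists, 16 of 35 divisions gave at least the real number of 15 and the highest other gave 23, so chance was not excluded for the number of lists.

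The first pattern is the fall of lymphatic and general endothelial genes beside the rise of matrix and macrophage genes. A smaller share of endothelial RNA in AKC tumors, acting alone on genes of endothelium only, would lower lymphatic and other endothelial genes alike. The lymphatic minus the general endothelial list mean differed by -1.23 (AKC minus AT, exact permutation p = 0.0286), with the AKC arrays at -0.29 to -1.51 and the AT arrays at 0.08 to 0.61. This order was already known from the list means, and genes also expressed by other cells or closer to background need not fall equally. The difference therefore does not decide about a smaller endothelial share. With quantile normalization 11 of the 13 lymphatic genes stayed lower past the threshold. The array distributions were already close, so this step could hardly undo falls with a median of -3.03. It is therefore a weak check on scaling of the arrays. Likewise, a smaller endothelial share alone would raise the markers of all other cell types. The macrophage minus the T and NK list mean was higher in AKC by 1.75 (exact permutation p = 0.0286), with the T and NK list itself lower. That order was known beforehand too, and a smaller endothelial share can go together with fewer T and NK cells. By camera at the preset correlation 4 lists of other cell types were higher and 1 lower among 14, and the MHC class II and dendritic cell list was lower too, but 0 of these 6 passed with an estimated correlation (adjusted p from 0.145 to 0.709) and the smooth muscle list had 0.173 with the muscle covariate. A mix of cells that differs by type cannot be told apart from a change within the tumor cells in whole-tumor RNA, and the genotype may contribute to either, which was not tested.

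The second pattern is skeletal muscle genes high in AKC replicates 1, 3 and 4. Of the 18 muscle genes, 17 had their lowest AKC value on AKC replicate 2, 16 of them by more than 1 on the log2 scale. On AT replicate 2, 12 of 16 keratinocyte genes had their highest AT value, 6 of them by more than 1. Both counts only describe what was seen, because the arrays were picked by the same genes. Whether muscle fibres or skin were part of these samples stays open, and no biological explanation was tested.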

How the results depend on the processing

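The settings with Eif2s3y or muscle as a covariate, and with both AKC replicate 3 and AT replicate 2 left out, were chosen only after the data were seen, and the planned Ddx3y covariate was not run. Across alternatives, values of single named genes stayed on their side of the threshold 2684 times, fell short of a call 350 times, gained one 11 times and changed sign 9 times. List tests kept their result 284 times, fell short 29 times and changed sign 1 time, and list means did so 137, 44 and 0 times. With an estimated correlation 0 lists passed camera. A change of at least 1 on the log2 scale left 1540 genes (637 higher, 903 lower) and an adjusted p under 0.01 left 1461 (516 and 945), both by construction. The muscle covariate gave 1989 genes (861 and 1128), and leaving both arrays out gave 2426, with 1012 higher and 1414 lower; the cause was not tested. With 3 arrays against 3 the smallest exact p is above the threshold, so list means were not tested there. Leaving out 1 array gave 2055 to 3594 genes, 751 to 1505 higher and 1304 to 2140 lower. The lowest were without AT replicate 4, followed by AT replicate 1 (2149, with 768 and 1381), and 824 were higher without AT replicate 3. Lists past camera ranged from 15 to 18, and list means at an unadjusted exact p under 0.05 from 5 to 17, with 6, 6, 7 and 5 without AT replicates 1 to 4. With 1 array left out the groups are unequal, and the opposite assignment can have a larger difference than the real one. The exact p can then exceed 0.05 even where the groups do not overlap. A list mean that fell short in this way need not have lost its separation. Signs changed for genes that were not called: Tsc1 was -0.0048 with the Eif2s3y covariate and -0.011 with both arrays out, and ran from -0.047 to 0.12 with 1 array out, being negative without AKC replicate 2 (-0.00060), AT replicate 1 or AT replicate 2 (-0.0060). Eif2s3y was -2.18e-16 with itself as covariate, by construction, -0.68 with the muscle covariate and -0.24 with both arrays out, and Xist was 0.86 with the muscle covariate. The skeletal muscle list had an adjusted p of 0.992 with its own mean as covariate, by construction. The sterol list lost its call with the dimmest 33.3% (0.0839) or 50% (0.0658) of genes left out, with fry (0.0914), with the muscle covariate (0.0694) and with both arrays out (0.0528). The MHC class II list lost it without the dimmest 50% (0.0905), with fry (0.0852) and with both arrays out (0.0549), the lysosome list without the dimmest 50% (0.0505), and the T and NK (0.0834), mitotic (0.108) and muscle lists (0.140) with fry. The replicate number as a block gave 3286 genes (1286 higher, 2000 lower), 2896 of them among the 3527, and 18 lists. The numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.08, 0.02, 0.05 and 0.21, and only AKC replicate 4 matched its own number best. Quantile normalization gave 3593 genes (3094 shared), array weights 4420, all probe sets 4727 and the Eif2s3y covariate 3482. The median difference was 0.052 over all genes, -0.013 without the dimmest 33.3% and -0.081 without the dimmest 50%, the last a move of -0.133. On average, dim genes were thus shifted towards higher values in AKC compared with brighter ones. The median of the olfactory receptor genes was 2.708, 2.849, 2.920 and 2.705 on AKC replicates 1 to 4 and 2.672 to 2.699 on AT arrays. It was thus raised mainly on AKC replicates 2 and 3, which also had the lowest array weights (0.432 and 0.322). What caused this shift was not tested. Signal near background limits what dim genes can show, so for those only bounds or no sizes were given.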

Other observations

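All tests in this part were chosen only after the result was seen, and some of them were redefined after a first version had been run, to leave out or add members or to add a condition. RNAs of the imprinted Meg3 to Mir409 region, a cluster of long noncoding RNAs, small nucleolar RNAs and microRNAs expressed from the maternal allele, were higher in AKC tumors. Of 51 measured, 39 were higher and 0 lower, and the median was 1.01. Of these, 12 lay below background on all 8 arrays, 8 of them among the 39. Over the other 39, 31 were higher and 0 lower, with a median of 1.30. Members of the cluster are neighbours and their probe sets may read shared longer transcripts, so these counts are not of independent RNAs. Besides AF357355, AF357425 and Rian, Mir493 was at least 4.42-fold higher, Meg3 at least 1.63-fold, and Mir409 was higher by 1.18 ± 0.19. The paternally expressed genes at the edges did not pass, with Dlk1 at 0.86 ± 0.34 (adjusted p = 0.127) and Dio3, below background on all AT arrays, at an adjusted p of 0.186. Dlk1 gained a call with array weights (1.13, adjusted p = 0.0199) and without AKC replicate 2 (1.22, adjusted p = 0.00557), and had an adjusted p of 0.0960 to 0.738 under the 17 other alternatives. All genes named in this part that are outside the stated rule were chosen after their values were seen.

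Of 25 imprinted genes measured outside the cluster, 8 were higher and 0 lower, with a median of 0.47, and 4 lay below background on all 8 arrays. The growth-related genes Mest (3.21 ± 0.61), Peg3 (2.43 ± 0.72), Peg10 (1.06 ± 0.14), Ndn (1.12 ± 0.25) and Cdkn1c (1.18 ± 0.30) were higher, Plagl1 was at least 2.79-fold and Zim1 at least 2.56-fold higher, and Igf2 differed by 1.66 ± 0.52 (adjusted p = 0.0612). Igf2 gained a call under 5 alternatives, with adjusted p from 0.0107 without AKC replicate 2 to 0.0496 without the dimmest 33.3% of genes. Single omissions ended the calls of Peg3 in 7 of 8 cases and of Plagl1, Zim1 and Cdkn1c in 6 each, and that of Ndn without AT replicate 1 or 3. With the muscle covariate the median of the 25 was 0.46, and 2 of them were called. The differences there were 2.45 for Mest, 1.08 for Peg10, 0.72 for Peg3, 0.57 for Ndn and 0.54 for Cdkn1c. Peg10 kept its call (adjusted p = 0.0140), and it ended for Peg3 (adjusted p = 0.429), Plagl1 (0.306), Cdkn1c (0.245), Zim1 (0.219), Ndn (0.161) and Mest (0.0862). All of these but Mest also lost their calls with both AKC replicate 3 and AT replicate 2 left out, with adjusted p from 0.0726 to 0.177. Peg3 was 6.29 on AKC replicate 2, the AKC array with the lowest muscle mean, against 9.15 to 10.27 on the other AKC arrays. The hypothesis of a shift of imprinted genes as a set gave a camera p of 0.000121 with the preset correlation and 0.0596 with an estimated one, or 0.0183 and 0.150 with the muscle covariate, so it stays open. In the first version, which included 2 genes of the cluster, 10 of 27 were higher and these p were 7.12e-06 and 0.0476.

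Genes of families known from the placenta were also among the higher ones. Ceacam15 was at least 8.55-fold higher, Prl2a1 at least 3.19-fold, Prl8a9 at least 1.61-fold and the cathepsin Cts8 at least 1.43-fold. Prl8a9 was below background on 2 AKC arrays as well, and Cts8 on 1. Psg22 was higher by 1.74 ± 0.45. Stfa2l1, of the stefin family, which is not counted here as a family of the placenta, was higher by 2.94 ± 0.40. Psg22 lost its call in 7 of 8 single omissions and Prl8a9 in 4, and with the muscle covariate Psg22 had an adjusted p of 0.221 and Cts8 of 0.0521. Of 20 prolactin family genes 6 were higher and 0 lower, 30% against 6.30% of other genes (Fisher's exact p = 0.00114, adjusted over 4 families p = 0.00455). Without Prl5a1, which prompted the test, 5 of 19 were higher (Fisher's exact p = 0.00552), which goes with the hypothesis that more of this family rose than of other genes. This test set the family against genes of any brightness, and dim genes as a whole were on average shifted up in AKC. A comparison with equally dim genes was not tested. Of the 19, 16 lay below background on all 8 arrays, 3 of them among the higher ones, and 2 of the 3 others were higher (Fisher's exact p = 0.0209 among genes above background on at least 1 array). With the muscle covariate the calls of Prl8a9 (adjusted p = 0.220) and Prl6a1 (adjusted p = 0.169) ended. Members of the family are neighbours and near-identical copies may share probe signal, so they are not independent. The Ceacam and Psg family (2 of 28 higher, Fisher's exact p = 0.697), placental cathepsins (1 of 9, p = 0.445) and stefins (3 of 14, p = 0.0544) did not pass.

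For the Meg3 to Mir409 cluster, a gain of a region reaching beyond Dlk1 and Dio3 is argued against, since the 10 measured genes before Dlk1 and the 10 after Dio3 had a median difference of -0.0263, with 18 of the 20 above background. Dlk1 and Dio3 were not counted, and a gain confined to the stretch between them was not tested. RNA from muscle is argued against, since with the muscle covariate the cluster's median was 0.92 with 22 members called, or 1.0 with 18 called over the members above background, and Rian kept its call (adjusted p = 0.00143). RNA from fibroblasts may contribute and cannot be told apart from the genotype here, because the matrix list mean followed the groups closely (r = 0.905). With it as a covariate the median was 0.43, also over the members above background, and 5 of the 39 called members kept their call, Rian among them (adjusted p = 0.0274). Counts of cluster members, here and with the muscle covariate, are not of independent RNAs.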
